A study of Mus musculus with 5 samples.

How the data were processed

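Chromatin immunoprecipitation with sequencing (ChIP-seq) was analysed for 5 mouse bone marrow libraries, 1 per group. The transcription factors Gfi1 and Irf8 and an input of sheared chromatin were from granulocyte-macrophage progenitors, sorted per the labels as lineage-negative CD117-positive Sca1-negative CD16/32-positive CD34-positive cells. The histone mark H3K4me2, which lies at promoters and enhancers, was from lineage-negative marrow, once labelled wild-type and once labelled Gfi1 knockout. The groups were taken from the titles. The deposited names of the Gfi1, input and Irf8 tag files carry the letters Tg, and those of the H3K4me2 tag files name granulocyte-macrophage progenitors, where the labels give lineage-negative cells. The labels mention no transgene, and the labels were followed.

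Bowtie2, HOMER and the mouse build mm9 are named in the submitters' processing notes, without versions. The authors deposited HOMER tag counts, 1 file per chromosome, with the position, strand, length and whole-number count of tags at each 5′ end. All 164 tag files matched the totals of the deposited tag information. For Gfi1 and Irf8 the authors also deposited HOMER peak lists, called per library against the same single input. Per the file headers, peaks were 500 bp wide and at least 1000 bp apart, with at most 1 tag counted per base. Peaks had to pass a false discovery rate of 0.001, and a fold of 4 and a Poisson p-value of 1e-04 over both the input and the surrounding 10000 bp, per the file headers. The score of a peak is the authors' tag number normalised to 10000000 tags, and its fold is the authors' ratio to input. Both are the authors' values and were used only to describe, rank or filter peaks within a list. The deposited p-value columns were not used for any test. The limits on the number of tags were 11 for Gfi1 and 19 for Irf8. Of 24503 putative Gfi1 peaks, 8171 were removed by the input filter and 3907 by the local filter. Of 11794 putative Irf8 peaks, 8597 and 711 were removed by these filters and 2 as too clonal.

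Tags were recounted with at most 1 tag per position and strand, shifted towards the fragment centre by 50% of the deposited fragment length estimate (246, 185, 227, 137 and 168 bp for Gfi1, input, Irf8, H3K4me2 labelled wild-type and H3K4me2 knockout). Mean tag lengths were 50.0 nt for the Gfi1, input and Irf8 libraries and 36.0 nt for both H3K4me2 libraries, so repeats are not equally mappable in both kinds of library. A tag at the same position with another length (46292 lines) was merged. Ratios to input are of tags relative to all unique tags of a library. Windows for H3K4me2 were 2 kb around the peak centre, and log2 ratios used a prior of 1 tag per library and autosomal totals. A window counted as marked above the 95th percentile of all 1236153 autosomal 2 kb bins of that library. Medians over sites have order-statistic 95% intervals. Each median was placed among 10000 random lists of the same size, drawn from bins more than 5 kb from any peak and matched on the summed tags of both libraries. The share of tags in peaks and other shares have exact Clopper-Pearson 95% intervals, and ratios have exact conditional intervals. Intervals of tag shares and of ratios cover counting error only, and amplified tags without molecular identifiers are not independent molecules. Intervals of medians and of shares of peaks cover the spread over sites and treat sites as independent. None of them covers variation between libraries.

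Peaks were compared by overlap of at least 1 bp with bedtools 2.31.1. Irf8 peaks were placed at random 1000 times on their own chromosome, in bins with at least 5 input tags, and in bins marked in the library labelled wild-type. Placement in knockout-marked bins and in bins matched on knockout H3K4me2 was added after the data were examined. The matched placements drew bins from all autosomes and X, so they did not keep the chromosome of a peak. An unchanged Gfi1 and Irf8 library was simulated against the real input by Poisson draws around the local input level. Windows were called with the tag limits of the headers and their fold and p-value over input. The filter over the surrounding 10000 bp was not applied to the simulated libraries. The other comparisons of the report and the alternatives of counting, windows, scaling, priors and peak filters were fixed before the data were examined. The use of input in place of the library labelled wild-type, marked windows from the knockout library, density profiles, tags of one factor at sites of the other, overlap by peak strength or mark, and most tests of explanations were added afterwards. With 1 library per group there is no replicate check, no p-value was computed, and each comparison is of libraries, not of conditions.

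Named sites were fixed by rule: per class, the 5 peaks with the highest authors' score on placed chromosomes, leaving out peaks with input tags over 5 times the median of the list, and, among windows with at least 50 H3K4me2 tags, the 10 highest and 10 lowest ratios. Shared sites were ranked in both lists. Positions are mm9. No mm9 gene annotation was used here, and the gene table used gives GRCm38.p6, so no peak was assigned to a gene, exon or promoter. The gene lists fixed beforehand (granulocyte, monocyte, dendritic, stem, erythroid, lymphoid, mast cell, interferon, antigen presentation, transcription factor, target and non-haematopoietic genes) were therefore not analysed here. On simulated counts for the 12239 windows at Gfi1 peaks, 100% of windows changed 4-fold in either direction and 1.56% of unchanged windows passed 2-fold. These counts were Poisson draws around a rate pooled over both H3K4me2 libraries. The 1.56% therefore covers counting error only and not differences between the libraries. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.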

Results

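Binding of Gfi1, a zinc-finger repressor needed for granulocyte development, and of Irf8, an interferon regulatory factor needed for monocyte and dendritic cell development, was mapped in granulocyte-macrophage progenitors, which give rise to both lineages. H3K4me2 was mapped in lineage-negative marrow labelled wild-type or Gfi1 knockout. Each of the 5 groups held 1 library. Total tags were 12339942 for Gfi1, 23889237 for input, 29180441 for Irf8, 25350496 for H3K4me2 labelled wild-type and 34901415 for H3K4me2 in the knockout. After copies of a position and strand were removed, 6754844, 22316952, 18408986, 19721867 and 16264575 tags remained in the same order. Copies made up 45.3% of Gfi1 tags, 6.58% of input tags, 36.9% of Irf8 tags, 22.2% of the tags labelled wild-type and 53.4% of knockout tags. The Gfi1 library was thus the shallowest by unique tags, at a median of 14 tags per Gfi1 peak.

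The H3K4me2 libraries address the chromatin state at the binding sites and the effect of Gfi1 loss on it, but per the labels in other cells. Knockout-marked below means marked in lineage-negative marrow labelled Gfi1 knockout, not in the progenitors where binding was mapped. The knockout library carried the mark in sharp blocks, and the library labelled wild-type did not. The 1% of 2 kb autosomal bins with most tags held 22.5% of knockout tags (22.5 to 22.5, exact 95% interval), 2.85% of input tags (2.85 to 2.86) and 2.65% of the tags labelled wild-type (2.64 to 2.66). In the 12388 bins at or above the 99th percentile of the knockout library, knockout tags were 10.3 times the input (10.3 to 10.3), and tags labelled wild-type were 0.627 times the input (0.624 to 0.630). Counting copies, these ratios were 6.17 (6.15 to 6.18) and 1.16 (1.16 to 1.16). The input came from sorted progenitors and had longer tags, so it is not a matched input of the H3K4me2 libraries. Relative to their own means over all bins, these bins held 22.5 times the knockout tags, 2.19 times the input tags (2.18 to 2.19) and 1.37 times the tags labelled wild-type (1.36 to 1.37). Bins with at least 100 tags numbered 19052 in the knockout library, 132 in the input and 125 in the library labelled wild-type. The label of the latter library is therefore written out at each comparison. Every knockout ratio to it below sets an enriched library against one without measured enrichment beyond that of the input.

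**Figure D1:**
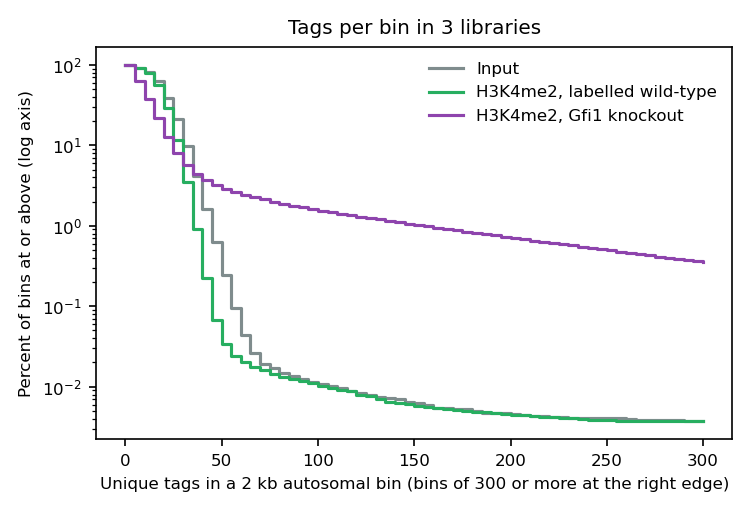
Percent of autosomal 2 kb bins (vertical, log axis) with at least the number of unique tags on the horizontal axis, for input, H3K4me2 labelled wild-type and H3K4me2 in the Gfi1 knockout; values of 300 or more are joined at the right edge. The knockout curve runs far to the right, with 19052 bins at 100 tags or more, while the library labelled wild-type, with 125 such bins, falls at lower tag numbers than the input.

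The targeted gene itself was not read, because Gfi1 is placed on chromosome 5 by a gene table of another build. A scan for stretches of at least 1500 bp without knockout tags, flanked on both sides by at least 20 tags within 1500 bp, found 172 such stretches. Chromosome 5 held 11 of them, or 6.40%, and 6.17% of all bins. The longest was 5886 bp, on chromosome 17 from 84568262 to 84574147, and the longest on chromosome 5 was 4285 bp, from 30237997 to 30242281. The scan did not single out a deletion, so the knockout label was not checked by it.

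Gfi1 occupied many more called sites than Irf8 in the progenitors. The authors' lists held 12425 Gfi1 peaks and 2484 Irf8 peaks. Gfi1 peaks were densest on chromosomes 19 and 11, at 7.43 and 7.11 per Mb, and sparsest on X, at 1.01 per Mb. Irf8 peaks followed the same extremes, with 1.68 per Mb on chromosome 19 and 0.222 per Mb on X, a chromosome that had 0.441 times the autosomal input coverage per unmarked bin. Gfi1 peaks held 3.02% of Gfi1 tags (3.01 to 3.03) against 0.492% of input tags (0.489 to 0.495). Irf8 peaks held 0.443% of Irf8 tags (0.440 to 0.446) against 0.0787% of input tags (0.0776 to 0.0799). Summed over peaks, Gfi1 exceeded input 6.13-fold (6.09 to 6.18) and Irf8 exceeded input 5.63-fold (5.53 to 5.72). Per peak, the exact interval of the ratio to input lay above 1 at 12101 Gfi1 and 2444 Irf8 peaks. The authors kept peaks at least 4-fold over this same input, per the file headers, so these ratios are largely set by that filter. A recounted ratio of at least 5 was reached at 7849 Gfi1 peaks and 1390 Irf8 peaks. The depths and tag limits of both lists differed, so the peak numbers do not rank the factors by number of sites.

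The 5 highest-scored Gfi1 sites without an Irf8 peak all lay in chromatin marked in the knockout library. The first was on chromosome 3 from 120994727 to 120995227 (mm9), with an authors' score of 417.3 normalised tags and 226 Gfi1 tags against 15 input tags, a ratio of 49.8 (29.5 to 90.4). Irf8 tags there numbered 13, or 1.05 times the input (0.460 to 2.37). The largest ratio of the 5 was 102 (42.7 to 318), on chromosome 16 from 91729438 to 91729938, with 154 Gfi1 and 5 input tags. The other 3 were on chromosome 13 from 113230185 to 113230685 (ratio 56.5), chromosome 6 from 115469517 to 115470017 (46.3) and chromosome 8 from 122625194 to 122625694 (37.8). Knockout H3K4me2 in the 2 kb windows of the 5 sites ranged from 89 to 280 tags.

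Of the 5 highest-scored Irf8 sites without a Gfi1 peak, 3 lay below the marked limit of knockout H3K4me2. Of all autosomal Irf8-only sites, 54.1% lay above it (51.8 to 56.4). Of the 100 highest-scored autosomal Irf8 peaks, shared ones included, 83.0% did (74.2 to 89.8). On chromosome 9 from 109855940 to 109856440 the authors' score was 155.9, with 216 Irf8 tags against 7 input tags, a ratio of 37.4 (17.8 to 94.2), while the 2 kb window held 5 knockout H3K4me2 tags. Chromosome 7 from 111552971 to 111553471 had a ratio of 36.6 (16.5 to 101) and also 5 knockout H3K4me2 tags. A second site on chromosome 7, from 13522558 to 13523058, had a ratio of 30.5 (12.8 to 95.7) and 15 such tags. The median autosomal bin held 7 knockout tags and the marked limit was 32. The remaining sites of the 5, on chromosome 2 from 18926400 to 18926900 and chromosome 17 from 47905568 to 47906068, had Irf8 ratios of 10.7 and 7.80 with 72 and 560 knockout H3K4me2 tags.

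Whether the opposed lineage factors meet at the same sites was asked by overlap. An Irf8 peak overlapped 657 Gfi1 peaks, which was 5.29% of Gfi1 peaks (4.90 to 5.70) and 26.4% of Irf8 peaks (24.7 to 28.2), taken over the 656 pairs on placed chromosomes. Overlap was more frequent among stronger peaks. Of the Gfi1 peaks in the lowest 25% by score 3.51% overlapped (2.89 to 4.22), and in the highest 25% 7.22% (6.33 to 8.19). For Irf8 the shares were 16.4% (13.6 to 19.6) in the lowest and 33.1% (29.4 to 36.9) in the highest 25%. The 25% just below the highest had 33.4% (29.7 to 37.3). In knockout-marked windows 36.2% of Irf8 peaks overlapped a Gfi1 peak (33.9 to 38.7), and outside them 9.31% did (7.50 to 11.4). Marked windows rose with score from 48.6% to 90.5% of Gfi1 peaks between the lowest and highest 25%, and from 39.1% to 81.8% for Irf8. Peak strength and mark were therefore not separated.

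Random placement of the Irf8 peaks gave a mean of 13.6 overlaps (range 2 to 27 over 1000 placements) in any bin and 14.0 (5 to 28) in bins marked in the library labelled wild-type. In knockout-marked bins the mean was 169 (128 to 214), so the observed number was 3.88 times that mean. Independent lists would fall in the same fixed window, of 5277938 windows of 500 bp, 5.83 times, a stricter event than an overlap of 1 bp, for which placement gave the 13.6 above. Simulated unchanged libraries against the shared input gave 75 Gfi1 and 122 Irf8 calls, 55 of them in common. These calls were made without the authors' filter over the surrounding 10000 bp. How many would pass it was not tested, so they do not measure the part due to the shared input. Part of the excess may come from the shared input, since both lists used the same single input library.

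**Figure D2:**
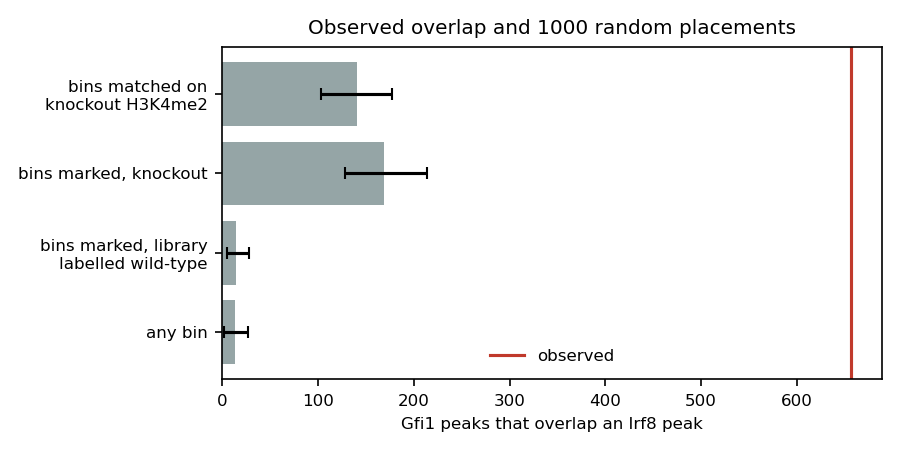
Number of Gfi1 peaks that overlap an Irf8 peak (horizontal): the line is the observed 656 on placed chromosomes, bars are means of 1000 random placements of the Irf8 peaks and whiskers their lowest and highest values. Placement in knockout-marked bins gave the highest mean, 169, and no placement reached the line.

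Each factor also left tags at sites called for the other alone. At the 11752 Gfi1-only sites, Irf8 tags were 1.44 times the input (1.43 to 1.45), against 1.00 (0.994 to 1.01) in windows away from peaks matched on knockout H3K4me2 tags in 2 kb. At the 1825 Irf8-only sites, Gfi1 tags were 2.65 times the input (2.58 to 2.72), against 1.38 (1.34 to 1.43) in such windows. The match was incomplete in the 500 bp that were counted. Knockout H3K4me2 there was 6.82 times the input at Gfi1-only sites and 6.19 in their windows, and 4.14 at Irf8-only sites and 3.44 in theirs. At the 656 shared sites Gfi1 was 7.57-fold (7.33 to 7.82) and Irf8 4.84-fold (4.69 to 4.99) above input. These are sums over each class, and single sites differed: the Irf8-only site on chromosome 7 from 13522558 to 13523058 held 1 Gfi1 tag, 0.661 times the input (0.0140 to 5.91).

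The shared site with the highest Gfi1 score lay on chromosome 19 from 8094402 to 8094902, with 89 Gfi1, 136 Irf8 and 5 input tags, ratios of 58.8 (24.3 to 186) and 33.0 (13.8 to 103). It was also among the 5 highest by Irf8 score, from 8094363 to 8094863. The next shared sites by Gfi1 score were on chromosome 15 from 59575872 to 59576372, chromosome 17 from 36973866 to 36974366, chromosome 9 from 40589886 to 40590386 and chromosome 18 from 61268136 to 61268636. Their Gfi1 ratios ranged from 6.16 to 29.4 and their Irf8 ratios from 3.03 to 5.12. By Irf8 score the first was on chromosome 2 from 127834379 to 127834879, with 197 Irf8, 40 Gfi1 and 8 input tags but 1 knockout H3K4me2 tag in 2 kb. The second, on chromosome 9 from 96299734 to 96300234, had 164 Irf8, 33 Gfi1 and 19 input tags and 4 knockout H3K4me2 tags. The others were on chromosome 13 from 52667779 to 52668279 and chromosome 11 from 3005274 to 3005774, the latter inside a 50 kb window with 15.5 times the median input coverage.

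**Figure D3:**
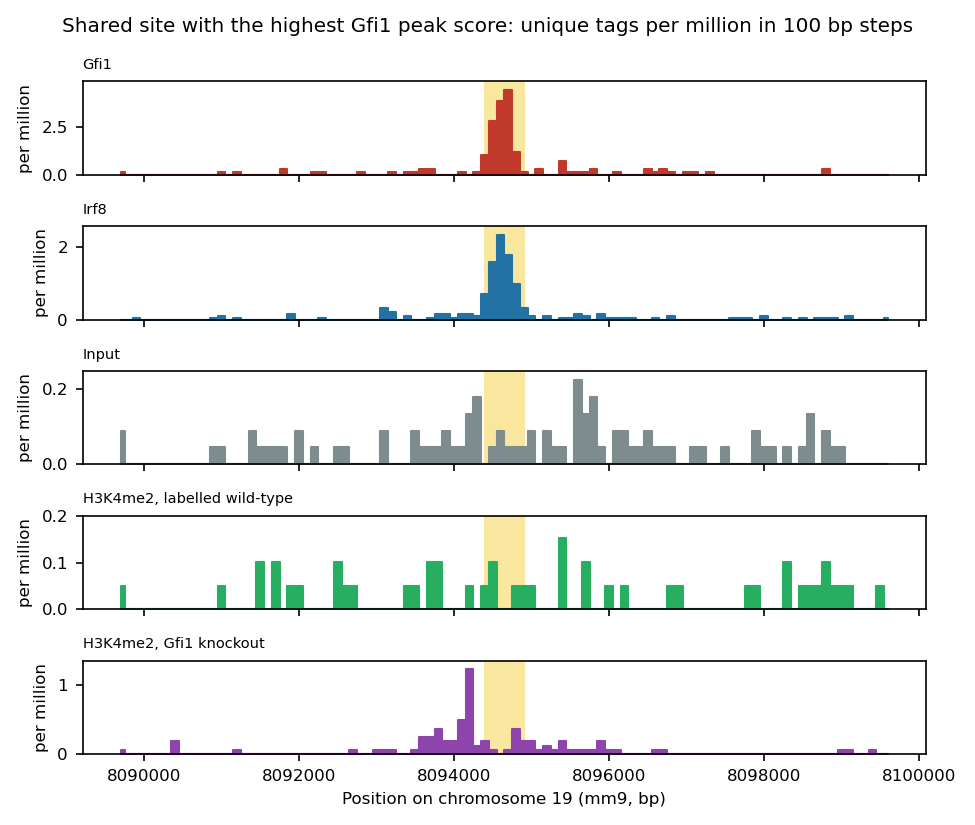
Unique tags scaled to library size in 100 bp steps (vertical, own scale per row) of the 5 libraries around the shared site with the highest Gfi1 score, on chromosome 19; the shaded band is the Gfi1 peak from 8094402 to 8094902. Gfi1 and Irf8 tags pile up in the band, where 5 input tags were counted.

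H3K4me2 in the knockout library was high at most sites of both factors. A marked window was found at 71.6% of Gfi1-only (70.8 to 72.4), 86.4% of shared (83.5 to 88.9) and 54.1% of Irf8-only autosomal sites (51.8 to 56.4), against 4.82% of all bins. The input also exceeded the 95th percentile of its own bins at many of these windows, at 39.9% of Gfi1-only (39.1 to 40.8), 38.9% of shared (35.2 to 42.8) and 22.7% of Irf8-only sites (20.8 to 24.7), against 4.96% of all bins. In the library labelled wild-type the shares were 4.49% (4.12 to 4.89), 3.71% (2.39 to 5.47) and 5.40% (4.40 to 6.55), against 4.57% of all bins. The density of knockout tags within 200 bp of the centre was 1.17 times that at 300 to 600 bp at Gfi1-only sites, 0.990 times at shared sites and 0.991 times at Irf8-only sites. The input had values of 1.11, 0.976 and 0.974 in the same order, so the classes differed in a like way without the antibody.

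**Figure D4:**
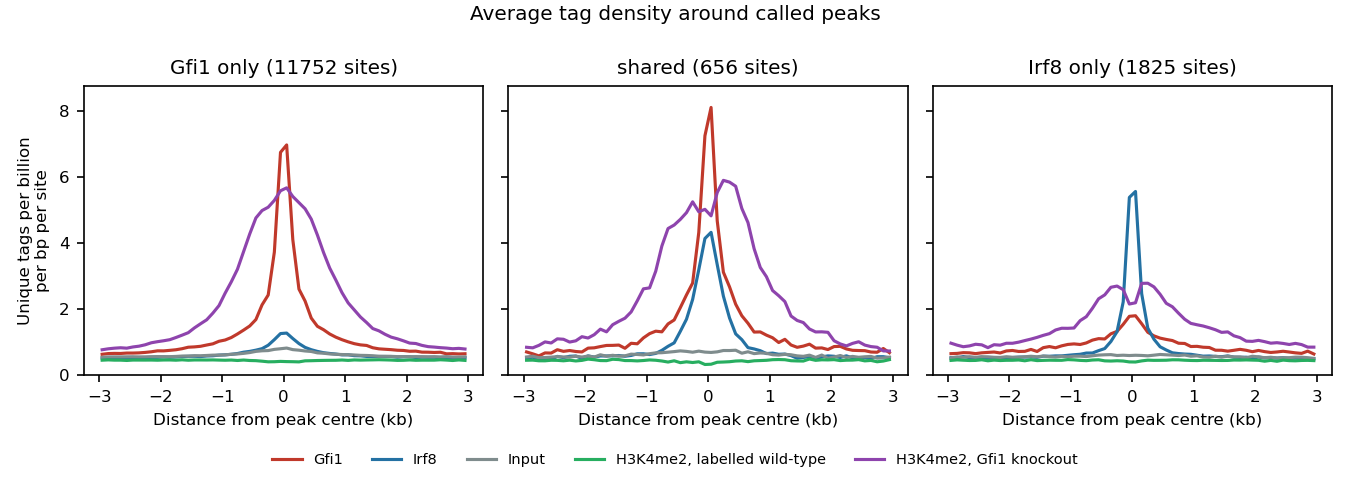
Average density of unique tags (scaled to library size, per bp and per site) within 3 kb of the peak centre for the 5 libraries, in the 3 classes of sites; lines are means over sites. Knockout H3K4me2 rises in all classes, while the library labelled wild-type stays flat or dips, at 0.905, 0.826 and 0.932 times its flanks for Gfi1-only, shared and Irf8-only sites.

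The knockout library therefore stood above the library labelled wild-type at all 3 classes of sites. The median log2 ratio was 2.57 at Gfi1-only sites (2.52 to 2.63, n = 11592), 2.93 at shared sites (2.77 to 3.06, n = 647) and 1.26 at Irf8-only sites (1.17 to 1.38, n = 1797). Medians of random lists matched on tags were 2.12, 2.55 and 0.42, and each observed median lay at the 100th percentile of its lists. Matching on summed tags leaves little room for the knockout tags to differ, and the tags labelled wild-type were low at these sites, with median log2 ratios to input of -0.64, -0.70 and -0.40 against -0.01, -0.01 and 0.01 in lists matched on the tags of that pair. The percentile therefore does not show a gain in the knockout. Over input in place of the library labelled wild-type, the medians were 1.87, 2.23 and 0.93, and matched lists had medians of 1.75, 2.08 and 0.49. Of 11903 Gfi1 peak windows with at least 20 tags, 9010 (75.7%) were at least 2-fold higher in the knockout and 317 (2.66%) at least 2-fold lower. In bins away from peaks, 5.76% were higher and 27.5% lower. When marked bins away from peaks were set to a ratio of 1, a shift of 1.37 on the log2 scale, the numbers were 6590 and 1823 and the Irf8-only median was -0.10 (-0.20 to 0.01). When background bins were set equal, a shift of -1.35, they were 11069 and 29.

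The 10 largest ratios, among 10055 windows with at least 50 tags, had log2 values of 6.39 to 7.90 and were at 8 Gfi1-only sites, 1 shared site and 1 Irf8-only site. They held 178 to 904 knockout tags and 0 to 11 tags labelled wild-type, against a median of 16 of the latter per 2 kb bin. The Gfi1-only site on chromosome 14 from 57504101 to 57504601 had 198 knockout tags, 0 tags labelled wild-type and 22 input tags, with an exact lower bound of the ratio of 63.8. The Gfi1-only site on chromosome 18 from 67550176 to 67550676 had 791 and 8 tags, a ratio of 119 (59.9 to 276). The Irf8-only site on chromosome 16 from 10785453 to 10785953 had 904 and 11 tags (98.7, 54.9 to 198), and the shared site on chromosome 5 from 134659854 to 134660354 had 233 and 2 tags (140, 38.3 to 1162). At the other end, the 10 lowest log2 ratios ran from -2.23 to -0.67. The lowest was the Gfi1-only site on chromosome 5 from 123897975 to 123898475, with 7 knockout tags, 44 tags labelled wild-type and 30 input tags (ratio 0.191, 0.0726 to 0.427). The next were Gfi1-only sites on chromosome 1 from 133078133 to 133078633 (0.360, 0.172 to 0.700) and chromosome 7 from 120092543 to 120093043 (0.422, 0.206 to 0.812). At the 4 weakest of these 10 the interval included 1. These intervals cover counting error only, and the comparison is of 2 libraries.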

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

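Tag levels on sequences outside the placed chromosomes were not compared in the report, although 17 Gfi1 and 3 Irf8 peaks on them entered the peak numbers and shares of tags in peaks, and both values here were examined only after the data were seen. The Gfi1 library was 3.12 times the input on the unplaced sequence of chromosome 4 (2.80 to 3.47, 682 against 723 tags), and 2.98 times with copies counted. Irf8 there was 1.32 times the input (1.19 to 1.46). The library labelled wild-type was 1.74 times the input on the unassigned sequence (1.70 to 1.78, 19686 against 12828 tags), and 7.35 times with copies counted (7.25 to 7.44), while the knockout library was 0.929 times the input (0.904 to 0.955). Of the 203305 tags labelled wild-type there with copies, 16983 lay at 1 position, so the value of 7.35 is not an even level over that sequence. The Gfi1 value on the sequence of chromosome 4 and the wild-type-labelled value on the unassigned sequence were picked out because the ratio to input lay above 1.5 with its interval.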

How the results depend on the processing

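Input in place of the library labelled wild-type, and the knockout library as the source of marked windows, were chosen after seeing the data. Of 59 alternatives over 13 results, 12 stayed the same, 46 moved and 1 reversed. Counts had to stay within 1.5 times the main count, and shares and medians within the main value's 95% interval, so small shifts of a precise value count as moved. The Irf8-only median log2 ratio changed sign, to -0.10 (-0.20 to 0.01), with marked bins set to 0, which subtracts a constant of 1.37, and its interval includes 0. That setting gave 1.203 at Gfi1-only and 1.56 at shared peaks. Background scaling gave 3.93, 2.62 and 4.28 at Gfi1-only, Irf8-only and shared peaks. In the same order, 1 kb windows gave 2.81, 1.49 and 3.10, 4 kb windows 2.07, 1.03 and 2.38, at least 50 tags 3.37, 2.24 and 3.21, a prior of 5 tags 2.34, 1.13 and 2.65, peaks at or above the median score 3.36, 1.90 and 3.31, and input as reference 1.87, 0.93 and 2.23. All tags as deposited gave 2.64 at Gfi1-only peaks. Gfi1 peaks at least 2-fold lower in the knockout numbered 497 with all tags, 1823 with marked bins set to 0, 29 with background scaling, 52 in 1 kb windows, 3 with at least 50 tags and 583 against input. Gfi1 peaks at least 2-fold higher stayed between 6590 and 11069 in all 7 alternatives. Marked shares at the 99th percentile, in the library labelled wild-type, were 0.673% (Gfi1-only), 0.155% (shared) and 1.00% (Irf8-only), and with the knockout library, at the 95th percentile, 71.6%, 86.4% and 54.1%. Tags in Gfi1 peaks were 3.16% with all tags and 2.97% without the shift; in Irf8 peaks 0.465% and 0.424%. Peaks at or above the median score numbered 6474 for Gfi1 and 1253 for Irf8, fewer by construction, and a recounted ratio of at least 5 left 7849 and 1390. The overlap was 298 with centres within 100 bp and 291 with peaks at or above the median score. Except where a setting removes sites by construction, the cause was not tested. Alternatives for gene lists and promoters were not run without mm9 gene positions. No paired analysis was possible because each group has 1 library. Depth limits what single sites show: a median Gfi1 peak held 14 Gfi1 tags and 8 input tags.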

Other observations

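Among Irf8 peaks on placed chromosomes, 37.3% had a Gfi1 peak centre within 5000 bp and 57.8% within 20000 bp, counting the 26.4% that overlapped one. No chance value was computed for these distances. The strongest peaks of both factors mostly lay in windows marked in the knockout library. The limit was passed at 88.0% of the 100 highest-scored autosomal Gfi1 peaks (79.98 to 93.6) and 83.0% of the 100 highest-scored Irf8 peaks (74.2 to 89.8). Of all autosomal peaks, 72.4% and 62.8% passed it. These shares do not give the mark in the progenitors where binding was mapped. Of the 2444 autosomal Irf8 peaks, 53 (2.17%, 1.63 to 2.83) had 3 or fewer knockout H3K4me2 tags in 2 kb, against 31.2% of all autosomal bins.

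The Gfi1 library stood above input in some windows of high input coverage and not in others. On chromosome 17 from 39950001 to 40000000, where input coverage was 11.6 times the median, Gfi1 was 3.54 times the input (3.41 to 3.68) and Irf8 1.197 times (1.15 to 1.24), and with copies counted Gfi1 was 3.50 times. Copies mattered more in other windows. Gfi1 fell from 2.79 to 1.38 times the input with copies counted on chromosome 2 from 98500001 to 98550000, and from 2.63 to 1.61 times on chromosome 9 from 3000001 to 3050000. On chromosome 11 from 3050001 to 3100000, at 31.3 times the median, Gfi1 was 0.986 times the input (0.952 to 1.02) and Irf8 1.16 times (1.13 to 1.19). Of the 5 Gfi1 peaks left out for high input, the highest-scored lay on chromosome 5 from 147072502 to 147073002, with 168 Gfi1, 178 Irf8 and 113 input tags.

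The tests below were chosen after the result, or values close to it, had been seen, except the coverage of X and the search of autosomal 500 kb windows, which were set before their values were known. The criteria for a gain at Gfi1 sites and for unenriched material were made stricter after their values were seen, and by these criteria alone both stayed open. The values in the preceding paragraphs were also chosen after the data were seen.

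The library labelled wild-type showed no H3K4me2 enrichment beyond that of the input. Low depth is argued against, since that library held 1.21 times the unique tags of the knockout library. A gain of the mark only at Gfi1 sites is argued against in this pair, since it would leave the mark elsewhere in the library labelled wild-type. That library had 125 bins with at least 100 tags, against 132 in the input. In knockout-marked bins more than 5 kb from any peak it was 0.793 times the input (0.791 to 0.795), and the knockout library was 3.91 times (3.90 to 3.92). Gfi1 was 1.42 times the input there (1.41 to 1.42), so these bins were not free of Gfi1. In the 5704 of them with Gfi1 at or below its mean, the values were 0.978 (0.971 to 0.986) and 2.08 (2.07 to 2.10). That choice of bins is partly set by counting noise. Unenriched material may account for the missing enrichment, as 2.65% of the tags labelled wild-type lay in that library's own top 1% of bins against 2.85% for input. Its ratio to input by unique tags fell from 1.02 in unmarked bins to 0.663 in the top knockout bins away from peaks. Over all top knockout bins it was 0.627 by unique tags and 1.16 (1.16 to 1.16) with copies counted. The value with copies may rest on few positions. On chromosome 2 from 98500001 to 98550000 the input held 2710 unique tags and 348073 with copies, and the library labelled wild-type held 19507 tags at 1 position of that chromosome. By unique tags the ratio lay below 1, but the input is not matched to this library, so unenriched material stays open. A failed precipitation, another antibody, a wrong label and a loss of the mark across the genome stay open, and the difference between genotypes is not readable from this pair.

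Gfi1 and Irf8 peaks overlapped more than random placements. Input at the centre of shared sites was 1.29 times its flanks and 0.976 times its level at 300 to 600 bp, so no deep dip was seen on average. An average over sites cannot show dips at some of them, so dips of the shared input stay open as a part of the cause. Common location in chromatin of like knockout H3K4me2 did not reach the observed number. Placements matched on that mark, without keeping the chromosome, gave a mean of 141 (range 103 to 177) against 656. The mark came from lineage-negative knockout marrow, so chromatin marked in the progenitors was not matched. Centres lay within 100 bp in 45.4% of overlapping pairs (41.6 to 49.3), against 20.1% by even spacing, which is consistent with short sites that hold both factors. Short accessible sites that shear or precipitate more readily would give the same spacing, so binding of both factors and local accessibility cannot be told apart here.

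The knockout H3K4me2 library had few tags on Y, 0.202 times the input (0.187 to 0.219), against 0.998 for the library labelled wild-type with tags of the same length. A pool of mostly female animals in the knockout library only is argued against by its X over autosome coverage in unmarked bins. This was 0.451, near the 0.441 of input, 0.447 of Gfi1 and 0.452 of Irf8. It was 0.878 times that of the library labelled wild-type, which had the highest value, 0.513. The low yield of unmarked autosomal bins, 0.651 times the input, lies above the Y value. Closed chromatin of the kind in the emptiest autosomal windows may explain part of it, as the lowest of 4740 windows of 500 kb was at 0.252 and the median at 0.844. No window reached the Y value, so the remainder stays open, including a difference of the animals on Y.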
